A study of Bos taurus with 4 samples.

How the data were processed

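Single-nucleus RNA sequencing was done on subcutaneous fat from the back and on intramuscular fat of 2 cattle from a commercial feedlot. Each animal gave 1 library per depot, so that there were 4 libraries, 2 per depot. Per the labels, nuclei were released by Dounce homogenisation, made into 10x Genomics libraries with kit chemistry 3.1, and sequenced on an Illumina NovaSeq. No treatment was given.

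Upstream of the files, per the file headers, counting was done with Cell Ranger 6.0.1. The submitters' processing notes name the genome build ARS-UCD1.2. The annotation release and whether intronic reads were counted are not given in the sources used here. The deposited matrices hold raw UMI counts per gene and barcode, with 1 matrix per library, and the values were whole numbers with totals that differed between barcodes. The features were 21861 Ensembl cattle genes, of which 4251 had no gene name. The gene table at hand was for ARS-UCD2.0, another assembly than that of the counts, so no gene coordinates are given. That table was used only to see which named genes overlap another gene, since UMIs of such genes can be counted for the wrong one.

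Nuclei with at least 200 detected genes and under 10% of UMIs from mitochondrially encoded genes were kept. Depth differed widely, with 105481 to 4006966 UMIs in the kept nuclei of a library, and each share below has an exact Clopper-Pearson 95% interval. Intervals and limits cover counting error only. A count of 0 was read as allowing up to 3 counts. Counts were scaled to 10000 per nucleus and log-transformed. Clusters were made with scanpy 1.11.5 and igraph 0.11.9 from 2000 variable genes, chosen with the library as batch, 30 principal components without integration, 15 neighbours and a Leiden resolution of 1.0. A cluster was named when at least 3 of a type's markers were among its 100 leading genes, and the names end in "-like" because they rest on markers alone. Of 18 clusters, 3 stayed unnamed. Scrublet was run on libraries with at least 500 nuclei. Its doublet caller did not work on these data: it called 12 of 874 nuclei in the subcutaneous library of animal 1, 0 of 6126 in that of animal 2 and 0 of 1774 in the intramuscular library of animal 1. Doublets were kept in the main analysis, as fixed beforehand. Their removal, run as an alternative, took out only those 12 nuclei, so it tested little.

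Nuclei of a library are not replicates, so UMIs were summed per library, over all nuclei or over those of a class, where a library held at least 10 of them. Depots were compared with edgeR 4.0.16 (filterByExpr, TMM scaling, quasi-likelihood F test) in R 4.3.3, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Fold changes are log2 of intramuscular over subcutaneous with the standard error (SE), from 2 libraries per depot unless said otherwise. The SE was derived as the absolute fold change over the square root of edgeR's F statistic, since edgeR gives none. In 4 classes the intramuscular library of animal 2 held fewer than 10 nuclei. Those comparisons set 2 subcutaneous libraries against 1 intramuscular library, whose spread was assumed to be that of the subcutaneous ones. On simulated data with 8-fold changes the test recovered 3.03% of changed genes in whole-library sums, 1.59% in adipocyte-like, 13.6% in progenitor-like, 59.4% in blood endothelial-like, 1.59% in macrophage-like and 34.9% in pericyte/smooth muscle-like nuclei. Where a group had a count of 0, its fold is given as a lower bound: the lowest library of the other group over the highest level that 3 counts give in a library of the group at 0. With 1 to 3 counts the ratio of pooled CPM (UMIs scaled to the same total in every library) is given with its counting interval. Shares of nuclei were compared by an exact two-sided permutation test, which cannot go below 0.33 with 6 arrangements of the libraries.

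The comparisons were those the depots imply. The model, filters, 22 pathway lists, 14 marker lists, alternatives and the rule for naming genes were fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01. Camera with an estimated correlation, and fry, were run beside it. The rule named up to 8 genes per direction with the largest changes past the threshold, at 50 CPM or more and with the depots apart. It fell back on the 3 smallest p-values where fewer passed. It also named the 3 members of each pathway list with the smallest p, the most expressed member of some lists, and fixed adipose genes. Of those, DPP4 passed the count filter in no comparison and TTN was not among the feature names. Genes outside the rule were chosen after their values were seen and are marked so. Genes of the muscle and adipocyte lists were also summed as shares of each class's UMIs.

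The alternatives were the animal as a block, the size factors and the test of DESeq2 1.42.0, other filters on genes and nuclei, doublet removal, other cluster resolutions, a class per nucleus, thinned counts, muscle nuclei left out, and each library left out in turn. Alternatives that left out the unnamed clusters or the genes higher in muscle fibre-like nuclei were chosen after seeing the data. The labels give both depots of an animal the same number. As a check of that pairing, the deviation of animal 1 from its depot's mean was correlated between depots across genes, which are not independent replicates. Pearson's r was -0.0890 over the 11143 genes of the whole-library sums and 0.125 over the 4458 genes of adipocyte-like nuclei. In adipocyte-like nuclei 420 genes had an unadjusted p under 0.05 between the animals in edgeR, against 164 between the depots. The model without the animal, fixed before the data were examined, stayed the main one, with the animal as a block beside it. Between 0 and 2 barcodes were shared by any pair of libraries.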

Results

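The data describe how nuclei of cattle fat differ between a subcutaneous depot on the back and the fat inside muscle. Nuclei kept were 874 and 6126 in the subcutaneous libraries of animals 1 and 2, and 1774 and 63 in the intramuscular ones. These held 1138601, 4006966, 2717458 and 105481 UMIs in the same order. Median UMIs per nucleus were 849, 518, 1100.5 and 805, and median genes per nucleus were 604, 294, 757.5 and 590. Mitochondrially encoded genes took 1.24%, 1.65%, 1.32% and 0.0133% of UMIs, so the intramuscular library of animal 2 stood apart by its near lack of them. The libraries also differed in muscle RNA. Skeletal muscle contractile genes took 4.86% and 18.8% of UMIs in the libraries labelled subcutaneous, against 0.00868% and 0.0180% in those labelled intramuscular. Every direction between depots below holds for the depot labels as given and would turn round if they had been exchanged in both animals.

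The first comparison asked which types of nuclei each depot held. Adipocyte-like nuclei, named from markers such as the lipase gene LIPE, made up 16.4% (95% interval 14.0 to 19.0) and 0.833% (0.620 to 1.09) of nuclei in the subcutaneous libraries of animals 1 and 2. In the intramuscular libraries they made up 42.6% (40.3 to 45.0) and 88.9% (78.4 to 95.4). Muscle fibre-like nuclei, named from markers such as the actin gene ACTA1, made up 12.0% (9.93 to 14.4) and 62.4% (61.2 to 63.7) of the subcutaneous libraries. None was found among the 1774 and 63 intramuscular nuclei, which allows shares of up to 0.169% and 4.76%. Satellite-like nuclei, which carry markers of muscle stem cells, were also seen in the subcutaneous libraries alone, at 1.03% and 1.60%. Nuclei of unnamed clusters took 13.7% and 20.01% of the subcutaneous libraries and were absent from the intramuscular ones.

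The mean adipocyte-like share was 8.60% ± 10.98 (SD, n = 2) in the subcutaneous and 65.8% ± 32.7 (SD, n = 2) in the intramuscular libraries. The difference of 57.2 percentage points was in the same direction in both animals, 26.3 in animal 1 and 88.1 in animal 2. Its exact permutation p was 0.33, the smallest that the design allows. Without one library at a time the difference ranged from 34.0 to 80.3 points, the lowest without the intramuscular library of animal 2. Muscle fibre-like nuclei were on average 37.2% ± 35.7 (SD, n = 2) of the subcutaneous libraries (exact permutation p = 0.33). Progenitor-like nuclei, the fibroblast-like cells from which adipocytes arise, differed by 8.05 points (exact permutation p = 0.667), and the sign turned without the subcutaneous library of animal 2 (-0.155) or the intramuscular library of animal 1 (-3.65). Blood endothelial-like nuclei differed by -3.64 points (exact permutation p = 0.667), which turned to 3.74 without the subcutaneous library of animal 1 and 5.82 without the intramuscular library of animal 2. Among nuclei with at least 500 genes the blood endothelial-like difference was -16.4 points, and the progenitor-like one reversed to -2.46. Macrophage-like nuclei differed by -2.36 points (exact permutation p = 1), which turned to 1.05 without the subcutaneous library of animal 1. Pericyte/smooth muscle-like nuclei differed by -3.79 points (exact permutation p = 0.667), with -5.79 to -1.79 without 1 library. Among the nuclei of the 5 named types that are not muscle, adipocyte-like nuclei took 22.3% and 5.22% of the subcutaneous and 42.6% and 88.9% of the intramuscular libraries. In the same nuclei blood endothelial-like ones took 30.2% and 45.9% against 20.5% and 1.59%, a difference of -27.0 points (exact permutation p = 0.33). Pericyte/smooth muscle-like and macrophage-like ones differed by -15.5 and -5.03 points in these nuclei (exact permutation p = 0.33 for each). Progenitor-like ones took 27.0% and 21.2% against 31.3% and 7.94%, a difference of -4.47 points (exact permutation p = 1), opposite in sign to that among all nuclei. Whether the nuclei of these 5 types in the subcutaneous libraries came from fat or from the muscle in those libraries was not tested. These shares may therefore not be of fat alone, and the comparisons within classes below have the same limit.

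**Figure D1:**
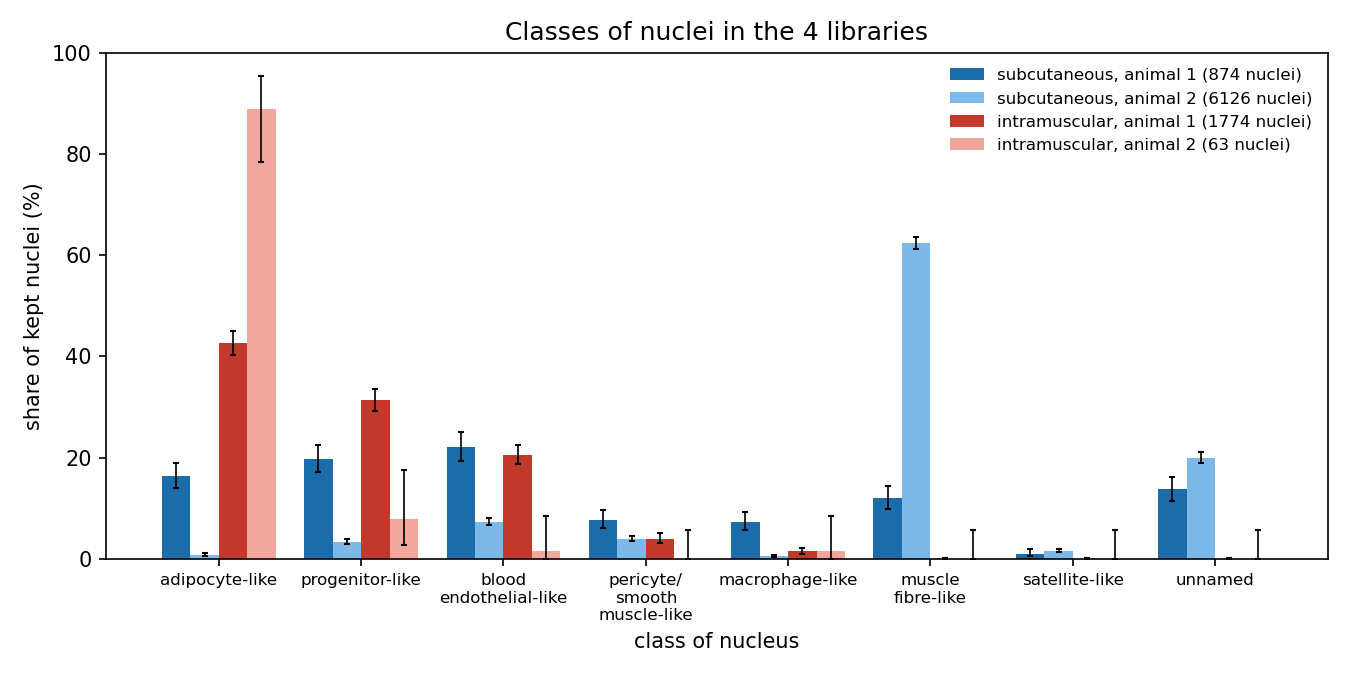
Share of kept nuclei (%, vertical axis) in each class of nucleus (horizontal axis) for the 4 libraries, with exact 95% intervals as error bars. Adipocyte-like nuclei are 42.6% and 88.9% of the intramuscular libraries and 16.4% and 0.833% of the subcutaneous ones, and muscle fibre-like nuclei appear in the subcutaneous libraries alone.

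Summed over whole libraries, skeletal muscle genes fell in the intramuscular depot and adipocyte genes lay higher without passing the test. TNNC1 and TNNT1, slow-fibre troponins, fell at least 68.0-fold and at least 57.4-fold, since no UMI of either was seen in the intramuscular libraries. EEF1A2, a muscle elongation factor, fell at least 17.7-fold, and the glycogen phosphorylase gene PYGM at least 16.5-fold. FABP3, the fatty acid carrier of muscle, chosen after its values were seen, fell by 6.06 on the log2 scale (SE 1.14). The leptin gene LEP had a log2 fold change of 2.04 (SE 0.98), the stearoyl-CoA desaturase gene SCD 2.72 (SE 1.91), LIPE 2.70 (SE 1.55) and ADIPOQ 0.94 (SE 0.88), none past the threshold. Among the 6 genes that rose were a transporter and a kinase anchor gene. SLC6A2, the noradrenaline transporter gene, rose by 5.23 (SE 1.12) with a pooled ratio of 40.1 (13.1 to 199), and AKAP4 by 5.51 (SE 1.17) with a ratio of 71.1 (23.7 to 350). FCGR2A, TDH and C5H12orf66, chosen after their values were seen, were also among them. In all, 199 of 11143 genes passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 6 higher and 193 lower. Without 1 library the count was 412 (subcutaneous, animal 1), 161 (subcutaneous, animal 2), 24 (intramuscular, animal 1) and 374 (intramuscular, animal 2). All 24 were higher, so no gene was called lower without the intramuscular library of animal 1. With muscle fibre-like and satellite-like nuclei left out of the sums, edgeR's count was 0, with 886 genes at an unadjusted p under 0.05. The unnamed nuclei stayed in those sums, and leaving them out as well, chosen after seeing the data, also gave 0 (807). DESeq2, run on the sums of all nuclei, called 344.

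By group, the contractile list had 17 tested genes, of which 2 (TNNT1 and XIRP2) fell over all genes tested and 17 adjusted over the list alone. The muscle fibre markers, largely the same genes, had the same 2 of 14 past the threshold and 14 adjusted over the list alone. Camera put both lower (adjusted p = 1.83e-40 and 1.93e-34; adjusted p = 0.458 for each with an estimated correlation). Satellite cell markers had 1 of 6 lower (NCAM1), and 4 adjusted over the list alone (camera adjusted p = 7.61e-04; adjusted p = 0.532 with an estimated correlation). The pericyte and smooth muscle markers had 2 of 14 lower (MYH11 and CNN1, named like NCAM1 after their values were seen), and 1 higher and 6 lower adjusted over the list alone (camera 0.00106; adjusted p = 0.458 with an estimated correlation). Genes of the respiratory chain, which muscle expresses strongly, lay lower with a median of -2.45 over 15 genes (camera 2.38e-06; adjusted p = 0.532 with an estimated correlation). The mitochondrially encoded genes lay lower with a median of -1.61 over 13 (camera 3.38e-04; adjusted p = 0.620 with an estimated correlation). Only 1 of them was lower in both intramuscular libraries than in both subcutaneous ones, and the fall rested on the intramuscular library of animal 2, with its 0.0133% of UMIs. Blood endothelial markers lay lower with a median of -0.84 (camera 0.0143; adjusted p = 0.756 with an estimated correlation). The adipocyte markers lay higher in 19 of 19 members with a median of 1.97 (camera 8.08e-11), as did lipolysis with a median of 1.66 (4.13e-05), de novo fatty acid synthesis with 1.53 (7.22e-05), triglyceride synthesis with 1.64 (7.61e-04), adipokines with 1.09 (0.0224), adipogenic transcription factors with 0.99 (0.0224), basement membrane with 1.02 (0.0125) and angiogenesis with 0.56 (0.0379). With an estimated correlation these 8 lists had adjusted p = 0.458 for triglyceride synthesis and adjusted p = 0.532 for each of the others. No member of these 8 lists passed edgeR's test over all genes or adjusted over the list alone. DESeq2 called 1 adipocyte marker, and 1 of the adipocyte markers had an unadjusted p under 0.05 in edgeR.

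The other lists tested in whole-library sums did not pass camera. Insulin signalling (median 0.73, adjusted p = 0.0605) had 1 member higher adjusted over the list alone, and fibrillar collagen and matrix (0.53, 0.0605) had 1 lower. WNT signalling (-0.76, 0.0695) and thermogenic genes (-0.25, 0.605) each had 1 member lower over all genes, DKK3 and UCP3, and fatty acid uptake had FABP3. TGF-beta and BMP signalling had a median of -0.61 (0.111), inflammation 0.30 (0.244), the steroid response 0.43 (0.583), fatty acid oxidation -0.51 (0.605), progenitor markers -0.62 (0.605), the HOX cluster 0.06 (0.766) and macrophage markers -0.92 (0.766). In 3 lists the median and the test had opposite signs: immediate early and heat shock genes (median 0.83, tested lower, 0.206), other patterning factors (-0.37, tested higher, 0.605) and fatty acid uptake (0.55, tested lower, 0.885). Of 29 lists, 15 passed camera, against 0 with an estimated correlation and 0 by fry, whose smallest adjusted p was 0.248. With the animal as a block, camera also passed fibrillar collagen (0.0234; adjusted p = 0.781 with an estimated correlation) and insulin signalling (0.0303; adjusted p = 0.682 with an estimated correlation). It no longer passed angiogenesis (0.0750). The marker lists of lymphatic endothelial (4 tested), T and NK (2), B (1), mast (2), Schwann (2), mesothelial (1) and erythroid (1) cells had fewer than 5 tested members and were not tested as lists. Of those genes 1 passed the test over all genes, the lymphatic gene MMRN1, which fell and was named after its values were seen.

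Within adipocyte-like nuclei, the positional gene HOXB8 and the muscle contractile genes fell in the intramuscular depot, and the genes of lipid storage and fat synthesis stayed without a call. HOXB8 (ENSBTAG00000054162), a HOX factor that marks position along the body axis, fell by 5.07 on the log2 scale (SE 0.88, adjusted p = 0.0195, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It had 155 ± 47.2 CPM (SD, n = 2) in the subcutaneous and 2.35 ± 3.32 CPM (SD, n = 2) in the intramuscular libraries. Its UMIs were few, 51 and 6 against 8 and 0, and HOXB8 overlaps HOXB9 in the gene table, so which of these genes its UMIs come from is uncertain. In animal 1 the subcutaneous level was 40.2 times the intramuscular one (18.9 to 98.0), and in animal 2, with 6 UMIs against 0, the lower limit of that ratio was 2.42. With the animal as a block HOXB8 fell by 5.24 (SE 0.97). Among nuclei with at least 500 genes it had a log2 fold change of -5.21 (SE 0.98) and lost its call (adjusted p = 0.0512 in edgeR). With thinned counts it fell under the count filter. Over its alternatives the adjusted p of HOXB8 ran from 5.62e-06 to 0.33, the highest without the intramuscular library of animal 2, where its fold change was -4.87 (SE 0.69), and without the subcutaneous library of animal 1 it fell under the count filter. The adipocyte-like nuclei came from different clusters: one held 130, 51, 8 and 56 nuclei of the libraries in the order used above, and the other held 13, 0, 748 and 0. HOXB8 was lower in the intramuscular libraries in each, at 182 and 122 against 0 and 0 CPM in the first, where the 8 nuclei were too few to show a difference at this depth, and at 246 against 4.73 CPM in the second. The HOX list had 1 of 11 tested genes lower over all genes and 1 adjusted over the list alone, with a median of -0.59 (camera adjusted p = 0.0262; adjusted p = 0.698 with an estimated correlation). HOXA9 had a log2 fold change of -2.09 (SE 0.93) and HOXB4 had 66.5 and 60.8 against 11.7 and 0 CPM, neither past the threshold.

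Apart from HOXB8, the genes that fell in adipocyte-like nuclei were more abundant in muscle fibre-like nuclei of both subcutaneous libraries. The fast myosin gene MYH2 fell at least 91.5-fold, the light chain genes MYL1 and MYL2 at least 23.5-fold and 22.4-fold, the creatine kinase gene CKM at least 16.98-fold and the slow myosin gene MYH7 at least 17.98-fold. ACTA1 had a pooled subcutaneous to intramuscular ratio of 2718 (750.3 to 22474). Of the 17 contractile genes, 14 fell over all genes tested and 17 adjusted over the list alone (camera adjusted p = 5.14e-19; adjusted p = 0.698 with an estimated correlation). Of the 14 muscle fibre markers 11 fell, and 14 adjusted over the list alone (camera adjusted p = 2.15e-15; adjusted p = 0.698 with an estimated correlation). These genes took 1.43% and 6.85% of the UMIs of subcutaneous adipocyte-like nuclei. In animal 1 a small part of the nuclei held most of these UMIs, and the median nucleus had 0.470%, against 0.760% in blood endothelial-like nuclei. They also took 1.47% and 8.54% in subcutaneous blood endothelial-like nuclei, a type that should lack them. Median depths were 1633 and 578 UMIs in the former and 952 and 615 in the latter. Of the 52 genes that passed in adipocyte-like nuclei, out of 4458 tested, all fell, and 51 of them were more abundant in muscle fibre-like than in adipocyte-like nuclei of both subcutaneous libraries. HOXB8 was the exception.

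The lipid genes showed no call in adipocyte-like nuclei. FASN, the fatty acid synthase gene, had a log2 fold change of 0.38 (SE 0.81), SCD 1.37 (SE 1.15), ACACA -0.14 (SE 0.76), GPAM 0.21 (SE 0.90), PLIN1 -0.04 (SE 0.83), LPL -0.25 (SE 0.90), CD36 -0.15 (SE 0.80) and FABP4 0.83 (SE 0.96). The adipokine genes LEP and ADIPOQ had -0.35 (SE 0.73) and -0.75 (SE 0.69), and the adipogenic regulator PPARG 0.23 (SE 0.78). DCN, a matrix proteoglycan gene, had 0.63 (SE 1.02), and its sign turned without the intramuscular library of animal 1 (-3.06). Of 12 tested genes of de novo fatty acid synthesis edgeR called 0 and DESeq2 0, with 1 at an unadjusted p under 0.05 (THRSP, a lipogenesis regulator, 1.96, SE 0.82). The list's median was 0.48 (camera 0.221, and 0.0352 with the animal as a block; adjusted p = 0.761 with an estimated correlation and the block). Triglyceride synthesis had a median of 0.61 over 11 genes (camera 0.218, and 0.0352 with the block; adjusted p = 0.761 with an estimated correlation and the block), and CIDEA, a lipid droplet gene of that list, had 2.96 (SE 0.96, adjusted p = 0.522 in edgeR). The steroid response list lay higher in 7 of 7 genes with a median of 0.91 (camera 0.0424; adjusted p = 0.698 with an estimated correlation, and 0.0509 with the block), led by TSC22D3 at 2.05 (SE 0.80) and ESR1 at 2.14 (SE 0.89).

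TBX3, a patterning factor, had 170 and 162 CPM in the subcutaneous and 643 and 1499 CPM in the intramuscular adipocyte-like nuclei, a log2 fold change of 2.72 (SE 0.84). It was the 1 member of 5 that passed adjusted over the list alone. Over all genes TBX3 had an adjusted p of 0.426 in edgeR, and over its alternatives 3.14e-04, without the intramuscular library of animal 1, to 1.00. CIDEA, which overlaps an unnamed model, likewise passed in edgeR without that library (3.90e-05), with a range of that value to 1.00. The smallest p-values among genes that lay higher belonged to ADAMTS4, a matrix protease gene (4.76, SE 1.06), GADD45B, a stress-response gene (4.14, SE 0.99), and MYOC (3.70, SE 0.94, pooled ratio 11.6, 3.92 to 56.9). Their adjusted p in edgeR was 0.0753, 0.114 and 0.165. ADAMTS4 passed with the animal as a block (6.26e-04), in DESeq2 (0.0246), with no filter on low counts (9.77e-04) and without the intramuscular library of animal 1 (4.64e-08), and its highest value was 1.00. Of the 22 lists tested 4 passed camera, the 2 muscle lists, HOX and the steroid response, against 0 with an estimated correlation and 0 by fry. Basement membrane (median 0.16, tested lower) and insulin signalling (-0.01, tested higher) had a median and test of opposite sign. The count of called genes was 61 without the subcutaneous library of animal 1 and 39 without that of animal 2. It was 345 without the intramuscular library of animal 1, of which 99 were higher, and without that of animal 2 it was 0 in edgeR, with 422 genes at an unadjusted p under 0.05. DESeq2 called 82 genes with all 4 libraries, and with the animal as a block edgeR called 86, of which 13 were higher.

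**Figure D2:**
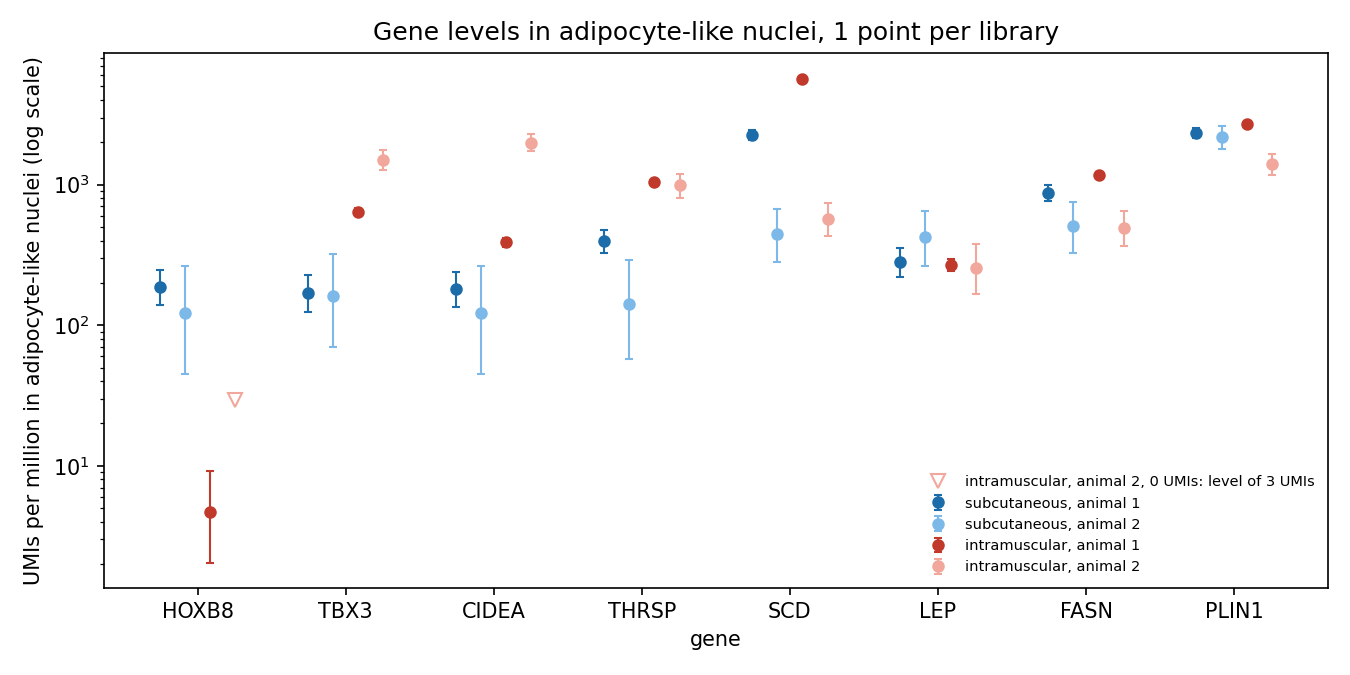
CPM (log axis, vertical) of selected genes (horizontal) in adipocyte-like nuclei, with 1 point per library, exact 95% intervals as error bars and an open triangle at the level of 3 UMIs for a count of 0. HOXB8 lies at 188 and 122 in the subcutaneous libraries and at 4.69 and 0 in the intramuscular ones, while TBX3 lies at 170 and 162 against 643 and 1499.

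Immediate early genes, which respond within minutes to stress, were set apart by 1 library. In adipocyte-like nuclei FOSB had 2007 CPM in the intramuscular library of animal 1 and 19.7 in that of animal 2, against 107 and 20.3 in the subcutaneous libraries. JUN had 6311 CPM in the same library and 927 in the other intramuscular one, against 2050 and 831. Of the 12 tested genes of the list, 9 were highest in the intramuscular library of animal 1, and 2 were higher in both intramuscular than in both subcutaneous libraries. Chance puts the libraries in that order for 1 gene in 6. The list had a median of 1.49 (camera 0.438, and 1.40e-07 with the animal as a block; adjusted p = 0.761 with an estimated correlation and the block).

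Progenitor-like nuclei were compared between 2 subcutaneous libraries and the intramuscular library of animal 1, with a further difference in clusters. One cluster held 162 and 207 subcutaneous nuclei and 2 of that intramuscular library, and the other held 11, 0 and 554. PI16, THBS4 and BMP4 were among the genes that fell. PI16, a marker of uncommitted progenitors, had a subcutaneous to intramuscular ratio of 52.2 (14.0 to 439), and THBS4, a matrix gene, fell at least 14.8-fold. BMP4, a growth factor gene, fell by 3.62 (SE 0.91), and IL33, an alarmin gene, by 2.86 (SE 0.77). SFRP4, a WNT modulator gene, had a ratio of 14.0 (4.37 to 71.6). These 5 genes were chosen after their values were seen. PI16 was among the leading genes of the cluster with 162 and 207 subcutaneous nuclei, so its fall cannot be told from that difference in clusters. Among the genes that rose, SEMA4A, a semaphorin gene, rose by 6.04 (SE 1.02) and ZFAND2A, a stress gene, by 5.04 (SE 0.85). SEMA4A was among the leading genes of the cluster with 554 intramuscular nuclei, so its rise has the same limit. GRP, a peptide hormone gene, rose at least 7.43-fold. It had 1781 CPM in the blood endothelial-like nuclei of that intramuscular library against 150 in the progenitor-like ones, so RNA from that other type is not excluded. The lipogenic genes SCD and THRSP rose by 4.47 (SE 1.36) and 3.77 (SE 0.80), and LEP rose by 3.51 (SE 0.76). Adipocyte markers took 1.45% of the UMIs of progenitor-like nuclei in that intramuscular library, against 0.358% and 0.0533% in the subcutaneous ones, and 1.48% to 3.06% in 3 other types of that library. The rises of fat genes therefore cannot be ascribed to the progenitor-like nuclei themselves. PDGFRA, the marker of these nuclei, had -1.35 (SE 1.15) and DCN -0.52 (SE 1.80), without a call. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 193 of 5193 genes passed, 61 higher and 132 lower, and 112 of the lower ones were more abundant in muscle fibre-like nuclei, such as CKM (at least 109-fold lower). With such genes left out 147 passed, 107 higher and 40 lower. With DESeq2's size factors in edgeR the count was 0, with 426 genes at an unadjusted p under 0.05, and DESeq2 called 87.

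In progenitor-like nuclei the gene groups followed the same genes. Adipocyte markers had 3 of 17 (SCD, LEP and CIDEC) higher over all genes and 7 adjusted over the list alone, with a median of 1.69 (camera adjusted p = 1.31e-06). De novo fatty acid synthesis had 4 of 12 (SCD, THRSP, ELOVL6 and ACSS2) higher over all genes, and 5 higher and 1 lower adjusted over the list alone (camera 0.0131). Fatty acid uptake had 1 of 10 higher (FABP5) and 2 adjusted over the list alone (camera 3.99e-04), adipokines 1 of 5 and 2 (0.00432), and triglyceride synthesis 1 of 10 and 2 (0.0207). The mitochondrially encoded genes lay higher in 13 of 13 (1.10e-05), immediate early genes lay higher with a median of 1.36 and 2 adjusted over the list alone (0.00569), and angiogenesis with 0.85 (0.0338). The contractile genes fell in 11 of 17, and 17 adjusted over the list alone (1.89e-06), as did muscle fibre markers in 9 of 14 and 14 (5.45e-05). All 10 of these lists had adjusted p = 0.782 with an estimated correlation. Fry called 2 lists, pericyte markers and insulin signalling (adjusted p = 0.0207 for both).

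Blood endothelial-like nuclei showed SCD, LEP and CCL8 higher and BMX, ACE and MMRN1 lower in the intramuscular library of animal 1, the only one of its depot with enough nuclei. The clusters differed here as well: one held 56 and 2 subcutaneous and 363 intramuscular nuclei, a second held 96 and 196 and 0, and another, with the lymphatic marker MMRN1, held 41 and 250 and 1. The chemokine genes CCL8 and CCL2 rose by 6.40 (SE 0.72) and 4.50 (SE 0.80), and SEMA4A by 5.43 (SE 0.64), while the chemokine gene CXCL5 fell at least 4.44-fold. SCD rose by 4.94 (SE 1.04), LEP by 4.22 (SE 0.59), FASN by 3.49 (SE 0.76) and PLIN1 by 2.87 (SE 0.64). BMX, a kinase gene of arterial endothelium, fell at least 41.9-fold, ACE, which makes angiotensin, at least 9.41-fold, and the water channel gene AQP1 by 2.70 (SE 0.70). The lymphatic markers MMRN1 and PROX1 had subcutaneous to intramuscular ratios of 23.5 (6.26 to 198) and 17.1 (4.50 to 145). CXCL5, BMX, ACE, AQP1, MMRN1 and PROX1 were chosen after their values were seen. BMX was among the leading genes of the cluster with 96 and 196 subcutaneous nuclei, and MMRN1 and AQP1 of that with 41 and 250. The falls of these genes therefore cannot be told from the near lack of intramuscular nuclei in those clusters. Lymphatic markers fell in 2 of 5 tested genes and in 5 adjusted over the list alone (camera 0.114). Of the 14 blood endothelial markers edgeR called 0 and DESeq2 0, with 3 at an unadjusted p under 0.05 and a median of -0.08. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 501 of 7634 genes passed, 198 higher and 303 lower, and 165 of the lower ones were more abundant in muscle fibre-like nuclei, such as TNNC2 (at least 281-fold lower). With such genes left out 295 passed, 167 higher and 128 lower. With DESeq2's size factors in edgeR the count was 0, with 883 genes at an unadjusted p under 0.05, and DESeq2 called 88.

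In blood endothelial-like nuclei many members of the fat lists rose. Adipocyte markers rose in 14 of 19 genes and in 17 adjusted over the list alone, with a median of 2.49 (camera adjusted p = 2.44e-45). De novo fatty acid synthesis rose in 9 of 12 and in 10 adjusted over the list alone, triglyceride synthesis in 6 of 10 and 7, lipolysis in 4 of 8 (such as LIPE) and 6, and adipokines in 3 of 7 (LEP, CFD and RBP4) and 4. Inflammation rose in 1 of 10 (CCL2) and in 1 adjusted over the list alone (camera 2.87e-05). The contractile genes fell in 17 of 17. Camera passed 16 of 28 lists, 13 higher and 3 lower, and the fat lists, inflammation and the contractile list had adjusted p = 0.587 with an estimated correlation, the smallest value of any list. Fry called 1 list, the HOX cluster (0.0202). The adipocyte markers also took a large share of UMIs in the other types of that intramuscular library. They took 3.06% in blood endothelial-like, 1.73% in pericyte/smooth muscle-like, 1.48% in macrophage-like and 1.45% in progenitor-like nuclei. Adipocyte-like nuclei of that library had 3.36%. The rises of fat genes therefore cannot be ascribed to the endothelial-like nuclei themselves. Nor can those of CCL2 and SEMA4A, which had 2668 and 1360 CPM in the progenitor-like nuclei of that library against 1958 and 245 in its blood endothelial-like ones. In the subcutaneous library of animal 2 the adipocyte-like nuclei had 1.75%.

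**Figure D3:**
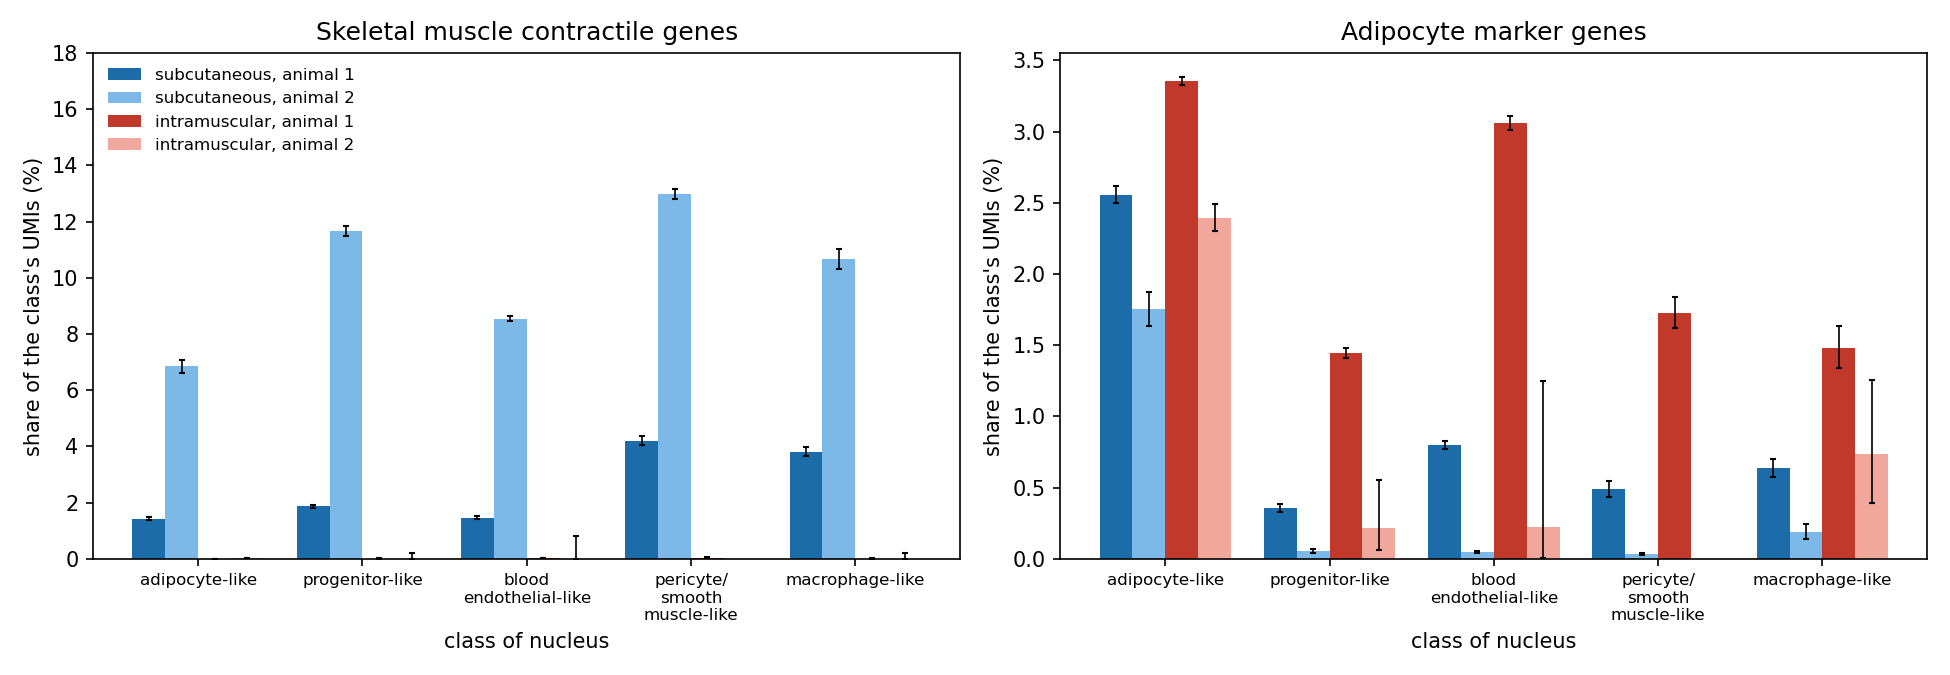
Share of each class's UMIs (%, vertical axes) from skeletal muscle contractile genes (left) and adipocyte marker genes (right) in 5 classes of nuclei (horizontal axes), for the 4 libraries, with exact 95% intervals. Contractile genes took 1.43% and 6.85% in subcutaneous adipocyte-like nuclei, and adipocyte markers took 3.06% in blood endothelial-like nuclei of the intramuscular library of animal 1.

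In macrophage-like nuclei (64, 31 and 27 nuclei) CXCL3 and FOSB rose and SPP1 fell in the intramuscular library of animal 1. The chemokine gene CXCL3 rose by 5.63 (SE 0.99), FOSB by 4.75 (SE 0.97), the chemokine gene GRO1 by 4.17 (SE 0.93) and SCD by 3.16 (SE 0.99). Adipocyte markers took 1.48% of the UMIs of macrophage-like nuclei in that library, against 0.634% and 0.186% in the subcutaneous ones. RNA from other types is therefore not excluded for SCD, and it was not tested for the other rises. SPP1, the osteopontin gene, fell at least 13.1-fold, and the lysosomal lipase gene LIPA, chosen after its values were seen, at least 3.29-fold. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 66 of 912 genes passed, 12 higher and 54 lower, of which 49 were more abundant in muscle fibre-like nuclei, and DESeq2 called 17. Contractile genes fell in 10 of 17 and in 14 adjusted over the list alone. Immediate early and heat shock genes had 2 higher (FOSB and EGR1) and 1 lower (HSPA1A) of 13, and 4 and 2 adjusted over the list alone (camera 0.00246). Adipocyte markers had 1 of 8 higher (SCD, camera 0.0461). Of 10 lists 4 passed camera, against 0 with an estimated correlation (adjusted p = 0.836 for each of the 4) and 0 by fry.

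In pericyte/smooth muscle-like nuclei edgeR called 0 of 1980 genes, with 282 at an unadjusted p under 0.05, while DESeq2 called 76. Smooth muscle genes lay lower in the intramuscular library of animal 1, with subcutaneous to intramuscular ratios of 186 (33.2 to 7338) for the myosin gene MYH11, 45.0 (15.3 to 219) for ACTA2 and 25.9 (7.07 to 215) for CNN1, all chosen after their values were seen. The clusters differed, one holding 52 and 238 subcutaneous nuclei and 0 intramuscular ones, the other 15, 2 and 71. MYH11, ACTA2 and CNN1 were among the leading genes of the cluster without intramuscular nuclei. Their ratios therefore cannot be told from a difference in which cluster each library held. CCL2 had 47.5 and 19.9 CPM in the subcutaneous libraries and 5091 in the intramuscular one (adjusted p = 0.206 in edgeR). Camera passed 9 of 13 lists, 5 higher and 4 lower, against 0 with an estimated correlation (smallest adjusted p = 0.608) and 1 by fry, immediate early genes (0.0419).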

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

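The tests that weigh explanations in this part were chosen only after the results were seen, while the comparisons between depots and the counts of classes were planned.

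Of the nuclei in the libraries labelled subcutaneous, 3930 were muscle fibre-like, 107 satellite-like and 1346 of unnamed clusters. These nuclei entered no comparison between depots, because the intramuscular libraries held 0 of each. That is the reverse of what the depot names would lead one to look for, since the fat inside muscle lies next to fibres. The subcutaneous shares of muscle fibre-like and unnamed nuclei lay above the limits of 0.169% and 4.76% that a count of 0 allows in the intramuscular libraries. Those of satellite-like nuclei lay above the first limit alone, so their absence from the intramuscular library of animal 2 says nothing.

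The muscle fibre-like nuclei of the subcutaneous libraries were weighed first. Shallow barcodes without a nucleus, which would thin out the share at a stricter filter, stay open. At 500 genes the share of muscle fibre-like nuclei was 1.02 times that at 200 genes in animal 2 and 1.72 times in animal 1. However, nuclei were clustered and named anew at 500 genes, and the difference of unnamed nuclei turned from -16.9 to 11.5 points. The ratios therefore mix depth with naming and cannot decide the question. Muscle taken along with the subcutaneous fat and an exchange of the depot labels, in both animals or in 1 animal alone, cannot be told apart. The intramuscular libraries held 0 muscle fibre-like nuclei, which speaks against an exchange in 1 animal only if muscle came with the same depot in both animals, and no value shows that. Satellite-like nuclei, at 1.03% and 1.60%, came with the fibre-like ones, which every reading predicts. An exchange in both animals would turn round every direction between depots, the adipocyte-like shares and the 199 genes of the whole-library sums included.

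The muscle transcripts in adipocyte-like nuclei were weighed next. Expression of contractile genes by subcutaneous adipocytes themselves is argued against, since these genes took no larger share of UMIs in adipocyte-like than in blood endothelial-like nuclei (ratios of 0.975 and 0.802). The median nucleus of animal 2 went the other way, with 9.34% in adipocyte-like against 8.28% in blood endothelial-like nuclei, and the medians of the other 3 types lay above both, from 9.46% to 13.4%. Doublets with a fibre nucleus were weighed by the contractile share of the median adipocyte-like nucleus over the pooled share. In animal 2 the ratio was 1.36, which argues against doublets in a minority of the nuclei as the source. Doublets in most of the nuclei would give such a ratio too and stay open. In animal 1, with 0.329, doublets stay open. Free muscle RNA in the droplets is a candidate explanation. Over 87 genes with at least 500 CPM in muscle fibre-like nuclei and at most 0.1 of that in intramuscular adipocyte-like nuclei, log2 CPM in subcutaneous adipocyte-like nuclei followed that in muscle fibre-like nuclei with r = 0.937 and 0.970. The other 4 types had 0.866 to 0.927 in animal 1 and 0.980 to 0.994 in animal 2. These are correlations across genes, which are not independent replicates, and doublets would give them too. So most of the 52 genes called in adipocyte-like nuclei may reflect muscle in the subcutaneous libraries and not the adipocytes. The like question for adipocyte genes in the other types of the intramuscular library of animal 1, where adipocyte markers took 1.45% to 3.06% of UMIs, was left open.

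HOXB8 in adipocyte-like nuclei was weighed last. Free RNA is argued against, since HOXB8 in subcutaneous adipocyte-like nuclei was 13.3 (6.49 to 30.8) and 88.3 (10.7 to 4062) times its level in the other types that are not muscle, from 51 UMIs against 9 and 6 against 1. A difference between the adipocyte-like clusters alone stays open. Within the shared cluster the lower subcutaneous level was 4.11 times what 3 counts give in the intramuscular library of animal 2. All adipocyte-like nuclei of animal 2 lie in that cluster, so this value restates its fall, from 6 UMIs to 0. In the other cluster animal 1 had 246 CPM in 13 subcutaneous and 4.73 CPM in 748 intramuscular nuclei, from 7 and 8 UMIs. A difference between depots in both animals stays open. The lower limits of the ratio, 18.9 in animal 1 and 2.42 in animal 2, cover counting error between single libraries and restate the fall that prompted the question. Also left open and not tested are UMIs of HOXB9, which overlaps HOXB8, and an exchange of labels.

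Across classes, 1 gene was called in opposite directions, the metallothionein gene MT2A, chosen after its values were seen. It rose by 3.38 (SE 0.74) in progenitor-like nuclei (38.8 and 0 CPM in the subcutaneous, 220 in the intramuscular library) and fell by 3.04 (SE 0.69) in blood endothelial-like nuclei (255 and 141 against 22.6 CPM). The difference between the classes was not tested. No biological explanation of it was tested either.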

How the results depend on the processing

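All alternatives were planned except the tests that leave out unnamed clusters or genes higher in muscle fibre-like nuclei, chosen after seeing the data. Without an exception named here, counts stayed within 1.5 times the main one. Unless a reason is given, the cause of a change was not tested.

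In whole-library sums (199 genes) DESeq2 called 344, no filter on low counts 444, a filter of 50 CPM 126 and thinned counts 90. Leaving out muscle fibre-like and satellite-like nuclei gave 0 in edgeR (886 at an unadjusted p under 0.05), and the unnamed clusters as well 0 (807). Without 1 library the count ran from 24 to 412, lowest without the intramuscular library of animal 1 (all 24 higher) and highest without the subcutaneous library of animal 1.

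In adipocyte-like nuclei (52 genes) the animal as a block gave 86 (13 higher), DESeq2 82, no filter 101, nuclei with 500 genes 19 and a class per nucleus 22. Thinned counts gave 0 in edgeR (55 at an unadjusted p under 0.05). With the genes higher in muscle left out the count was 0 (83), although HOXB8 kept its fold change of -5.12 (SE 0.87) against -5.07 (SE 0.88). Its adjusted p rose to 0.312 because the genes with smaller p-values were gone, in a range of 5.62e-06 to 0.33 over its alternatives. Without 1 library the count ran from 0 (422), without the intramuscular library of animal 2, to 345 (99 higher), without that of animal 1. DCN reversed to -3.06 without the intramuscular library of animal 1.

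In progenitor-like nuclei (193) DESeq2's size factors in edgeR gave 0 (426), DESeq2 87, a filter of 50 CPM 51, nuclei with 500 genes 85, a cluster resolution of 2.0 81, thinned counts 0 (377) and the genes higher in muscle left out 147 (107 higher and 40 lower). In blood endothelial-like nuclei (501) the size factors gave 0 (883), DESeq2 88, no filter 0 (761), 50 CPM 0 (463), 500 genes 0 (651), resolution 2.0 0 (707), thinned counts 160 and muscle genes left out 295 (167 higher and 128 lower). In macrophage-like nuclei (66) DESeq2 gave 17, no filter 0 (218), resolution 2.0 0 (127) and muscle genes left out 19. In pericyte/smooth muscle-like nuclei (0, with 282) the size factors gave 39, DESeq2 76, no filter 142, 500 genes 7, thinned counts 108 and muscle genes left out 170. In these 4 classes, with 1 intramuscular library, the block or leaving out a library left no residual degrees of freedom, so no value was had. The class per nucleus gave too few nuclei for them, as did 500 genes or a resolution of 0.5 for macrophage-like and all barcodes or a resolution of 2.0 for pericyte/smooth muscle-like nuclei.

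Of the shares, adipocyte-like nuclei kept a positive difference in every alternative (34.0 to 80.3 points without 1 library) and muscle fibre-like nuclei a negative one (-62.4 to -12.0). With 500 genes the progenitor-like difference reversed to -2.46 and that of unnamed nuclei to 11.5, the blood endothelial-like one grew to -16.4 and the macrophage-like one shrank to -1.27. A class per nucleus gave -71.2 for muscle fibre-like, -0.359 for unnamed, 2.46 for progenitor-like, -0.860 for macrophage-like and -1.54 for pericyte/smooth muscle-like nuclei. All barcodes gave -1.18 for macrophage-like and -10.3 for unnamed nuclei, and a resolution of 0.5 gave -5.52 for blood endothelial-like ones. Without 1 library, ranges were -3.65 to 19.8 for progenitor-like, -13.1 to 5.82 for blood endothelial-like, -5.77 to 1.05 for macrophage-like and -5.79 to -1.79 for pericyte/smooth muscle-like nuclei.

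Camera passed 15 lists in whole-library sums, against 0 with an estimated correlation and 0 by fry. In adipocyte-like nuclei it passed 4, against 7 with the block, 0 estimated, 0 by fry and 6 to 8 without 1 library. In progenitor-like nuclei it passed 10 against 0 and 2, in blood endothelial-like 16 against 0 and 1, in macrophage-like 4 against 0 and 0, and in pericyte/smooth muscle-like 9 against 0 and 1. Over 500 values of named genes and 5730 alternatives, 4789 kept their direction and side of the threshold, 695 lost a call, 176 gained one, 69 moved and 1 reversed. Named genes without a call in the main test had none to lose, as all of those in pericyte/smooth muscle-like nuclei. The 4789 therefore do not measure how firm the calls were. In blood endothelial-like nuclei 601 of 985 values kept their direction and side. Depth limits most the intramuscular library of animal 2, with 63 nuclei and 105481 UMIs.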

Other observations

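No test in this part was planned, and the values were picked after they were seen.

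The muscle in the subcutaneous libraries differed between the animals in its myosins. Of the UMIs of MYH1, MYH2 and MYH7, the fast IIx, fast IIa and slow forms, animal 1 had 2.28%, 62.2% and 35.6%, and animal 2 had 59.5%, 25.9% and 14.6%.

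In the intramuscular library of animal 1, SCD was close in every type, with 5687 CPM in adipocyte-like, 7411 in blood endothelial-like, 4251 in progenitor-like, 5091 in pericyte/smooth muscle-like and 4511 in macrophage-like nuclei. LEP had 269, 356, 209, 166 and 191 CPM in the same order. FOSB was higher in its progenitor-like nuclei (5175 CPM) than in its adipocyte-like ones (2007).

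The lower genes of the classes overlapped. All 51 of the genes lower in adipocyte-like nuclei that were also tested in blood endothelial-like ones were lower there as well, where 1.47 would be shared by independent lists. Between progenitor-like and blood endothelial-like nuclei 33 of the genes that rose were shared, against 1.79. These comparisons share their libraries, so the overlap is not independent evidence.

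In other groupings of the 4 libraries, pairing them by animal or across animals, 0 genes passed edgeR in whole-library sums (323 and 51 at an unadjusted p under 0.05), against 199 by depot (1152). In adipocyte-like nuclei they also gave 0 (420 by animal and 45 across), against 52 by depot (164), so more genes had a small p-value by animal than by depot. Splits this few cannot give a share under 0.05.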
